A study of Mus musculus with 4 samples.

How the data were processed

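The data are 4 Affymetrix Mouse Genome 430 2.0 arrays of hippocampal RNA from male DBA/2J mice, 2 control and 2 fluoxetine pools of 6 mice each. Groups and pool numbers were taken from the sample titles and treatment labels. The deposited table holds 1 intensity per probeset and array, on a linear scale, normalized by the authors with GCRMA in ArrayAssist, per the labels' design text. GCRMA corrects background by probe sequence, normalizes between arrays and summarises the probes of a probeset, and it pulls dim probesets towards a common floor. Software versions are not given in the sources used here. The submitters also describe an intensity minimum of 100 and a rule of at least 2-fold, with no statistical test.

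Values were kept as the authors normalized them and taken to log2 without a pseudocount, since all were above 0. Of 45101 probesets, 64 Affymetrix controls were left out, and a probeset was tested if it reached 100 in at least 2 of the 4 arrays, which left 16938 (37.6% of the others). Probesets were named from the platform annotation table: 34958 had 1 gene symbol, 932 several and 9211 none. Of those with 1 symbol, 34754 were found by gene number in the reference gene table, and 0 symbols changed. Among tested probesets 14954 had 1 gene, 423 several and 1561 none, and genes were named only from probesets with 1. A gene was represented by its tested probeset with the highest mean log2 value, giving 9030 genes, and list counts and list tests use that probeset alone unless stated. Of the 50 called genes named in the text or closing section, 16 had more than 1 tested probeset, and in all 16 the tested probesets had the same direction. Not all of these probesets passed: 1 of 4 did for Rgs5, 1 of 2 each for Drd1, Npc2 and Grin3a, and 4 of 5 for Sox11.

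Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no covariate), two-sided, with Benjamini-Hochberg adjustment over all tested probesets and a threshold of 0.05. An exact permutation test of 2 against 2 arrays cannot give a p under 0.333, so limma's moderated test, which borrows spread from all probesets, is the basis of each call. Group means are geometric, errors are limma standard errors of the log2 fold change, and n is the number of pools. Where all arrays of one group were under 100, the fold is written as at least the brighter group's mean over 100. The submitters' 2-fold rule was applied to ratios of geometric means. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 of 35 lists that had at least 5 tested members. Each list was also adjusted alone, and tested with an estimated correlation, with ranks and with fry.

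The tests, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule names the 12 largest rises and the 12 largest falls in measured log2 fold change, not in these lower bounds, among called genes whose groups do not overlap, leaving out clone and predicted-gene names, and up to 4 members of each list with the largest absolute change, with any member allowed for the mature and immature granule cell, serotonin and antidepressant candidate lists. A few further genes, named as such, were chosen after their values were seen. Lists cover dentate, pyramidal and interneuron markers, activity and peptide genes, receptors and channels, candidate and hormone genes, stress, metabolism and immunity, and markers of other cell types and neighbouring tissues. Some genes stand in more than 1 list.

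The procedure was tested on simulated data with the 16938 probesets of this comparison, in 10 runs with 200 changed probesets each. With 4 arrays it recovered 8.6% of changes of log2 0.5, 80% of log2 1, 96.8% of log2 2 and 98.8% of log2 3, and 5.01% of its calls were false. With 3 arrays it recovered 18% of log2 1 and 92.2% of log2 2. Simulated spreads were drawn from the distribution that limma fitted to these data, with normal noise independent between probesets and no batch. A false share near the threshold of 0.05 is therefore built in, and does not give the false share among calls in the data. Simulated lists held 15 of 9030 genes. Camera with the preset correlation called 10 of 10 that were shifted by log2 0.4 and 0 of 30 that were not. With an estimated correlation it called 0 of the 10. Simulated genes varied independently of each other, so these counts do not test the preset where genes of a list vary together. Estimated correlations of the lists that camera called in the data ran from -0.05 (neuropeptide) to 0.63 (interferon response).

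Alternatives were other intensity filters, quantile normalization, median centring, a floor of 100, a pseudocount of 32, leaving out each array, leaving out probesets that can match several transcripts, the pool number as a block, eBayes with trend and robust settings, array weights, a minimum fold of 1.2 (treat), an ordinary t statistic, an adjusted p under 0.10, genes as the unit, linear-scale means and other list tests. Hybridisation spike-ins and the 3' to 5' probesets of beta-actin and Gapdh were read as quality controls. The log2 3' to 5' difference of beta-actin was 1.37 and 1.43 in control and 1.38 and 1.46 in fluoxetine arrays, and that of Gapdh -0.42, -0.41, -0.43 and -0.40. The scanner files were not used here, so probe-level background and scan order were not examined.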

Results

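Hippocampal messenger RNA was measured in adult male mice of the inbred strain DBA/2J after 21 days of drinking water with or without fluoxetine, an antidepressant that blocks serotonin reuptake. The labels give a dose of 18 mg/kg per day for the treated mice and 0 for the controls. RNA from the bilateral hippocampi of 12 mice per group was combined into 2 pools of 6 mice, and each pool was hybridised to 1 Affymetrix Mouse Genome array, giving 2 control and 2 fluoxetine arrays. The submitters describe the pools as separate biological samples carried through the procedure apart from each other. The comparison asks which hippocampal transcripts differ after chronic fluoxetine. The median intensity over all probesets was 23.3 and 23.0 in the control arrays and 23.1 and 22.6 in the fluoxetine arrays, and between 16651 and 16905 probesets per array reached the submitters' intensity minimum of 100. The number of arrays limits the precision.

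Several secreted neuropeptide and growth factor genes and astrocyte filament genes rose in fluoxetine pools. Penk, which encodes the precursor of the enkephalin opioid peptides, rose from a mean intensity of 261 to 3486, a log2 fold change of 3.74 ± 0.08 (SE, n = 2 pools per group, adjusted p = 0.00217). Bdnf, the brain-derived neurotrophic factor, rose from 611 to 2721 (log2 2.16 ± 0.07, adjusted p = 0.00614), and Npy, neuropeptide Y, from 1332 to 6220 (log2 2.22 ± 0.10, adjusted p = 0.0172). Gfap, the intermediate filament of astrocytes, rose from 422 to 2898 (log2 2.78 ± 0.14, adjusted p = 0.0172). Among the falls, Dsp, a desmosomal plaque protein used as a marker of dentate granule cells, dropped from 728 to 210 (log2 -1.79 ± 0.24, adjusted p = 0.0495), and the serotonin receptor gene Htr1b from 203 to 89.3 (adjusted p = 0.0262). Both fluoxetine pools lay under the minimum of 100 for Htr1b, so its fold is a lower bound taken against 100, at least 2.03-fold.

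The genes named next were ranked by measured log2 fold change at each gene's brightest tested probeset, as fixed beforehand, and not by such bounds. Of the 12 largest measured rises among called genes, 7 started from control arrays that were all under 100. Against 100, Nptx2, a neuronal pentraxin of excitatory synapses, rose at least 3.72-fold (55.1 to 372), Inhba, the activin beta A subunit, at least 3.02-fold (40.9 to 302), and Blnk, an adapter of B cell receptor signalling, at least 2.81-fold (58.9 to 281). Gal, the galanin precursor, rose at least 2.67-fold (20.9 to 267), the collagen chain gene Col3a1 at least 2.31-fold (57.7 to 231), Olfm4 at least 2.09-fold (50.7 to 209), and the membrane peptidase gene Ecel1 at least 1.24-fold (32.6 to 124). The calcium-binding protein gene S100a6 rose from 321 to 1521 (log2 2.25 ± 0.11). Of the 12 largest measured falls, 6, Htr1b among them, ended in fluoxetine arrays that were all under 100. Psrc1 was at least 1.79-fold lower (179 to 78.1), Gabrd at least 1.73-fold (173 to 78.0), Trim62 at least 1.45-fold (145 to 79.5), the receptor tyrosine kinase gene Ltk at least 1.38-fold (138 to 60.9), and Zfp772 at least 1.17-fold (117 to 61.9). Fat4, an atypical cadherin, fell by 1.35 on the log2 scale, Lypd1 by 1.08, the fatty acid transporter Slc27a2 by 1.00, the orphan receptor Gpr12 by 0.89, and cytoglobin (Cygb) by 0.86. Adjusted p for these 24 genes lay between 0.00217 and 0.0495. An adjusted p under 0.05 and values of the groups that did not overlap were conditions of the rule.

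**Figure D1:**
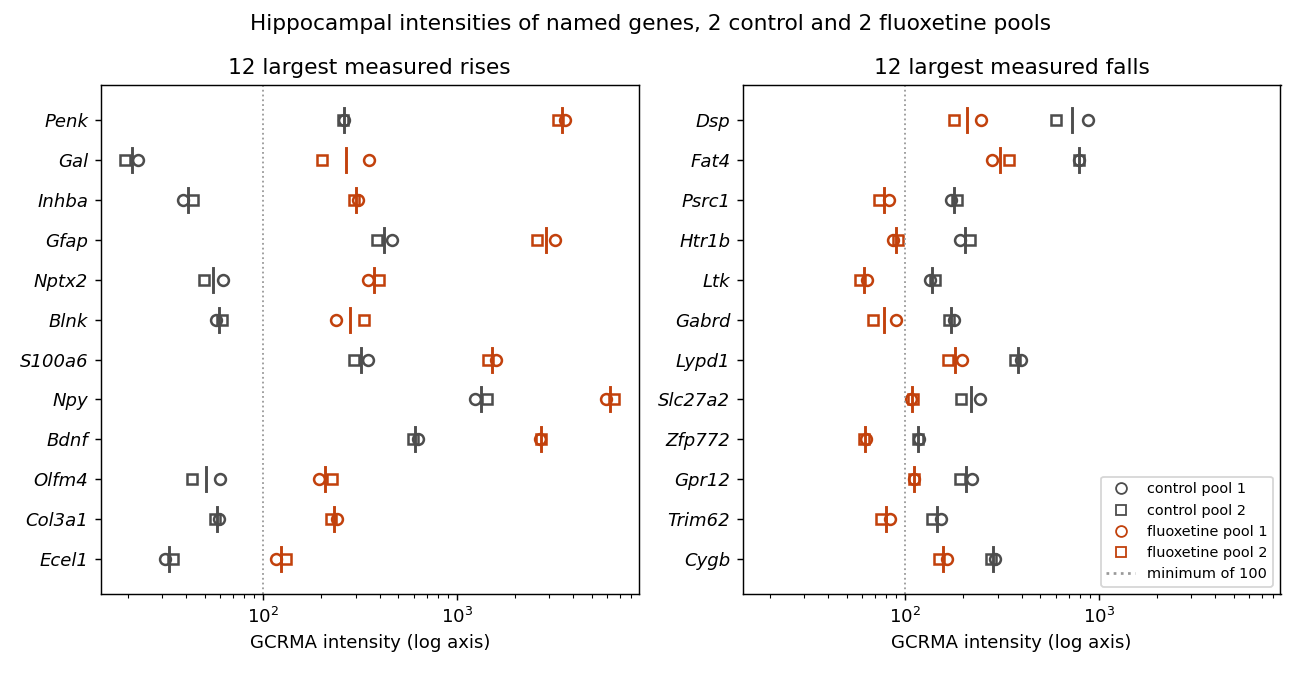
GCRMA intensity on a log axis of the 12 called genes with the largest measured rise (left) and the 12 with the largest measured fall (right). Open symbols are single pools, circles for pool 1 and squares for pool 2, vertical bars are geometric group means, and the dotted line is the intensity minimum of 100. Penk went from a mean of 261 to 3486, while 7 of the risen genes lay under 100 in both control pools.

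In all, 291 of 16938 tested probesets differed at a Benjamini-Hochberg adjusted p under 0.05 by limma, 175 higher and 116 lower in fluoxetine pools, and 3816 had an unadjusted p under 0.05. Counted at each gene's brightest tested probeset alone, 168 genes passed, 118 higher and 50 lower. Genes that passed only at another probeset are not in this count. The submitters' own 2-fold rule took 134 probesets, 113 higher and 21 lower, of which 90 also passed limma, and 133 had groups that did not overlap. Among all tested probesets 56.0% had groups that did not overlap, against 33.3% by chance. Splitting the arrays by pool number gave 8 probesets at 2-fold, and the remaining split gave 2. limma called 0 probesets in each of these splits, with 217 and 235 at an unadjusted p under 0.05. Each side of these splits holds 1 control and 1 fluoxetine pool, so the group difference enters the residual spread and lowers such counts beforehand. The limma counts of these splits are therefore no measure of how many of the 291 calls would arise by chance. Pools of one group differed less (SD of log2 differences 0.189 and 0.198) than pools of different groups (0.280 to 0.299). With any array left out, the adjusted test called 0 probesets, with 2657 to 3515 at an unadjusted p under 0.05. With values floored at 100, Gal, Ecel1, Dsp, Ltk, Zfp772 and Trim62, among the genes named here, no longer passed. All 18 hybridisation spike-in probesets, whose RNA is added to each sample in fixed amount, were also higher in both fluoxetine arrays than in both controls, by a median log2 of 0.36 (0.17 to 0.55), while the median over tested probesets was -0.04 and that of 7 other bacterial controls -0.02. The labels used here give no order of hybridisation or scanning, so a batch that followed the groups, which would shift this comparison too, is not excluded.

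Of 13 tested neuropeptide genes, 6 rose and 0 fell, with 7 higher and 1 lower when adjusted over the list alone. Besides Penk, Gal and Npy these included Scg2 (log2 0.98 ± 0.09) and Vgf (log2 0.80 ± 0.08), a granin and a granin-like precursor, and the list median was 0.59. The list was higher than other genes by camera (adjusted p = 4.18e-06), with adjusted p = 0.341 with an estimated correlation. Of 13 neurotrophic and growth factor genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone): Bdnf, Inhba, Nptx2, Vgf and Gadd45b (log2 1.28 ± 0.12), a stress-inducible gene with a role in DNA demethylation. The median was 0.33 (adjusted p = 4.35e-07 by camera, adjusted p = 0.341 with an estimated correlation). Of 16 immediate early genes, 2 rose and 0 fell, the same counts as when adjusted over the list alone: Egr3 (log2 1.09 ± 0.10, adjusted p = 0.0352) and Fosl2 (log2 0.70 ± 0.07). Fos itself was at 268 and 230 in the control pools and 483 and 1039 in the fluoxetine pools, a log2 difference of 1.51 ± 0.37 that did not pass (adjusted p = 0.117), and Arc (log2 0.85 ± 0.26, adjusted p = 0.162) did not either. The scaffold gene Homer1, chosen after its values were seen, counts as not passed at its brightest probeset (log2 0.12 ± 0.08, adjusted p = 0.405), but 1 of its 5 tested probesets rose by log2 2.92 ± 0.19 (adjusted p = 0.0252), the other 3 lying between -0.04 and 0.11. The immediate early list had a median of 0.12 (adjusted p = 0.0485 by camera, adjusted p = 0.755 with an estimated correlation). Its call was lost without control pool 2 (adjusted p = 0.182), its test changed direction without fluoxetine pool 2 (adjusted p = 0.922), and quantile normalization (adjusted p = 0.0939), median centring (0.0963), no intensity filter (0.0935) and camera on ranks (0.0900) ended the call too.

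Granule cell markers of the dentate gyrus moved in both directions. Of 15 tested mature granule cell genes, 1 rose, the Ras-like GTPase gene Rasl10a (log2 0.96 ± 0.12, adjusted p = 0.0466), and 1 fell, Dsp, with 3 higher and 4 lower when adjusted over the list alone. The calcium buffer gene Calb1 was at 5014 in control and 3661 in fluoxetine pools (log2 -0.45 ± 0.08, adjusted p = 0.0771), and of its 3 tested probesets 1 passed, at -1.16. C1ql2 (log2 1.11 ± 0.17, adjusted p = 0.0636) and Npnt (log2 0.72 ± 0.14, adjusted p = 0.0865) were higher without passing. The list median was -0.00 and camera made no call (adjusted p = 0.958). Of 15 immature granule cell and neuroblast genes, 1 rose, Sox11, a transcription factor of newborn neurons, from 259 to 601 (log2 1.21 ± 0.06, adjusted p = 0.0172), with 4 of its 5 tested probesets passing. Adjusted over the list alone, 3 were higher and 1 lower. Tubb2b (log2 0.43 ± 0.07, adjusted p = 0.0636), Marcksl1 (log2 -0.49 ± 0.10, adjusted p = 0.0927) and doublecortin, Dcx (log2 -0.28 ± 0.12, adjusted p = 0.266) did not pass, and the list did not either (adjusted p = 0.219). Neural stem cell and cell cycle genes had 6 tested members, 0 calls by limma over all probesets and 0 over the list alone (camera adjusted p = 0.901, median 0.04, mean -0.00049). Most of the 20 annotated genes of this list were too dim to be tested, Mki67, Top2a and Nes among them. The absence of calls therefore says nothing about those genes. CA pyramidal neuron genes had 11 tested members and 0 calls in either way (adjusted p = 0.635), with Fibcd1 at log2 -0.82 ± 0.25 (adjusted p = 0.162). Of 14 interneuron genes only Npy rose, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.674).

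Among receptors, 1 of 7 tested serotonin system genes changed, the fall of Htr1b. Adjusted over the list alone 2 were higher and 2 lower. Htr4 (log2 0.58 ± 0.10, adjusted p = 0.0755), Maoa, a monoamine oxidase (log2 0.31 ± 0.06, adjusted p = 0.0926), and Htr1a (log2 -0.31 ± 0.09, adjusted p = 0.152) did not pass over all probesets. The list made no call (camera adjusted p = 0.934, test upward, median 0.03, mean -0.11). Only 1 dopamine and noradrenaline gene was tested, the dopamine receptor gene Drd1, which rose from 142 to 471 (log2 1.73 ± 0.13, adjusted p = 0.0262). Of 12 GABA system genes 1 fell, Gabrd, the delta subunit of the GABA-A receptor, and 1 was lower adjusted over the list alone (camera adjusted p = 0.934, test upward, median -0.03, mean -0.08). Of 16 glutamate receptor genes 1 fell, Grin3a (log2 -0.72 ± 0.10, adjusted p = 0.0495), and 1 was lower over the list alone (camera adjusted p = 0.119). Of 21 genes on the voltage-gated ion channel list 0 rose and 1 fell, Kcnk2 (log2 -0.68 ± 0.08, adjusted p = 0.0448), which encodes a background potassium channel and is not a classical voltage-gated member. Over the list alone 1 was lower (camera adjusted p = 0.125). The 20 synaptic vesicle and postsynaptic scaffold genes gave 0 calls by limma in either way at their brightest probesets, Homer1 being among them, with Camk4 at log2 -0.45 ± 0.08 (adjusted p = 0.0726), and camera made none (adjusted p = 0.738).

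Of 17 antidepressant candidate genes, Bdnf and Vgf rose and Kcnk2 fell, with 4 higher and 4 lower when adjusted over the list alone. S100a10, which encodes the serotonin receptor partner p11, was at log2 0.62 ± 0.10 (adjusted p = 0.0683) and the glucocorticoid receptor gene Nr3c1 at -0.32 ± 0.07 (adjusted p = 0.0966). The list made no call (camera adjusted p = 0.708, test upward, median -0.01, mean 0.13). Of 15 glucocorticoid response genes 1 fell, Tsc22d3 (log2 -0.71 ± 0.07, adjusted p = 0.0352), with 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.934).

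Microglial, astrocytic and vascular marker lists were higher in the fluoxetine pools. So were the spike-ins, by a median log2 of 0.36, while the median over all tested probesets was -0.04. All 10 tested microglia genes had a log2 fold change above 0, 4 rose and 0 fell (8 and 0 adjusted over the list alone), and the median was 0.67. The complement gene C1qb rose by log2 1.10 ± 0.08, the tetraspanin gene Cd53 by 0.86 ± 0.10 and the immune adapter gene Tyrobp by 0.81 ± 0.07, while Ly86 (log2 1.13 ± 0.19, adjusted p = 0.0692) did not pass. The microglia list passed camera (adjusted p = 8.65e-09), with adjusted p = 0.341 with an estimated correlation. Of 16 astrocyte genes 3 rose and 0 fell (4 and 1 adjusted over the list alone): Gfap, the filament gene Vim (log2 1.78 ± 0.17) and the water channel gene Aqp4 (log2 1.07 ± 0.08). Fgfr3 lay in the other direction (log2 -0.44 ± 0.10, adjusted p = 0.110). The glutamate transporter gene Slc1a2, chosen after its values were seen, did not pass at its brightest probeset (log2 0.11 ± 0.06), while 1 of its 3 tested probesets rose by 0.76 ± 0.10 (adjusted p = 0.0494). The astrocyte median was 0.12 and its mean 0.39 (adjusted p = 0.00873 by camera, adjusted p = 0.427 with an estimated correlation), and the call was lost on ranks (adjusted p = 0.0597) and with no intensity filter (0.0526). Of 12 endothelial and mural genes 2 rose and 0 fell (9 and 1 adjusted over the list alone), the pericyte genes Rgs5 (log2 0.59 ± 0.06) and Abcc9 (log2 0.52 ± 0.07). For Rgs5, 1 of 4 tested probesets passed, all 4 being higher. The tight junction gene Cldn5 was at 0.66 ± 0.11 (adjusted p = 0.0707), and the median was 0.36 (adjusted p = 5.32e-06 by camera, adjusted p = 0.427 with an estimated correlation). Of 8 meninges and fibroblast genes Col3a1 rose, with 2 higher adjusted over the list alone (camera adjusted p = 0.101), and Col1a2 was at log2 0.83 ± 0.14 (adjusted p = 0.0711). The 15 oligodendrocyte and myelin genes gave 0 calls by limma in either way and none by camera (adjusted p = 0.674). Of the choroid plexus list only 3 members were tested and 0 passed. The transthyretin gene Ttr, the most abundant product of that tissue, was at 37856 and 2002 in control pools 1 and 2 and at 51101 and 4429 in fluoxetine pools 1 and 2. Of the blood list 0 members were tested.

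**Figure D2:**
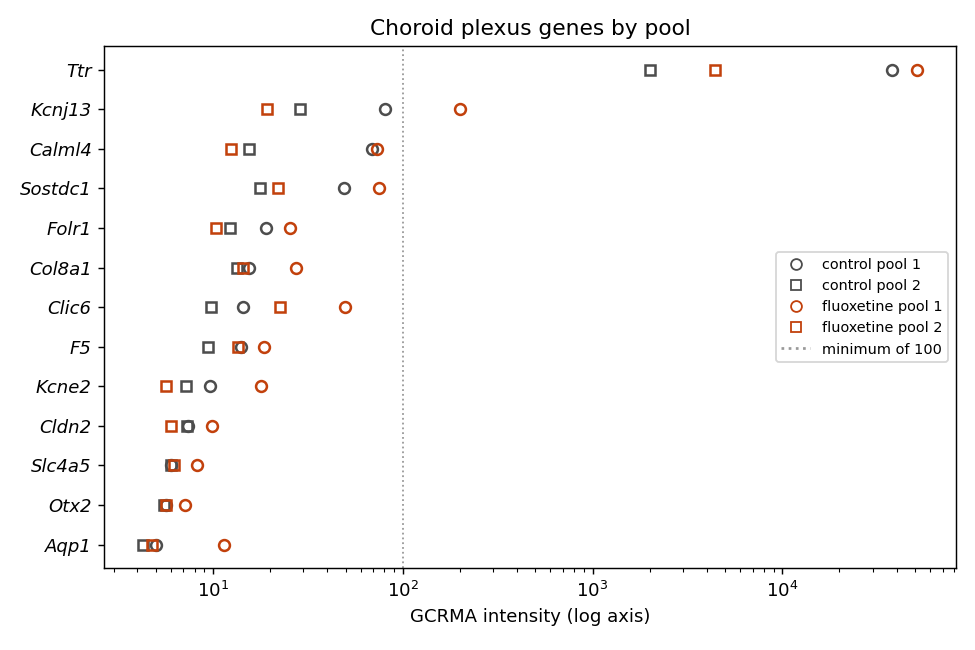
GCRMA intensity on a log axis of Ttr and 12 further choroid plexus genes, each at its brightest probeset. Kl and Ecrg4, left out of the test on choroid plexus genes, are not shown. Circles are pools numbered 1 and squares pools numbered 2, grey for control and orange for fluoxetine, and the dotted line is the minimum of 100. Ttr was at 37856 and 51101 in the pools numbered 1 and at 2002 and 4429 in the pools numbered 2.

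The lysosome, cholesterol synthesis, interferon response and heat shock lists were also higher than other genes by camera. Of 15 lysosome genes 2 rose and 0 fell (5 and 0 adjusted over the list alone): the protease gene Ctss (log2 0.61 ± 0.07) and the cholesterol carrier gene Npc2 (log2 0.56 ± 0.07), with Lipa at 0.57 ± 0.08 (adjusted p = 0.0507). The median was 0.21 (adjusted p = 5.32e-06 by camera, adjusted p = 0.427 with an estimated correlation). Of 14 cholesterol synthesis genes 0 passed by limma over all probesets and 5 were higher over the list alone, among them Nsdhl (log2 0.59 ± 0.11) and Sqle (log2 0.39 ± 0.10). Their median was 0.28 (adjusted p = 4.18e-05 by camera, adjusted p = 0.427 with an estimated correlation). Of 5 interferon response genes 0 passed over all probesets and 4 were higher over the list alone. Ifit3 was at log2 0.85 ± 0.28, and H2-D1 (0.66 ± 0.10, from a probeset that can match related genes) and B2m (0.51 ± 0.07) encode parts of the class I antigen presentation complex. These counts use each gene's brightest probeset, and 1 of the 5 tested H2-D1 probesets passed, at log2 0.79 ± 0.07 (adjusted p = 0.0341). The interferon median was 0.59 (adjusted p = 0.000521 by camera, adjusted p = 0.527 with an estimated correlation). Of 12 heat shock genes 0 passed and 1 was higher over the list alone, Hsph1 (log2 0.55 ± 0.09), with Bag3 at 65.5 in control and 137 in fluoxetine pools, at least 1.37-fold, which did not pass (adjusted p = 0.113). The heat shock median was 0.11 (adjusted p = 0.0479 by camera, adjusted p = 0.497 with an estimated correlation), a call lost without control pool 1 (adjusted p = 0.0763), with quantile normalization (0.138), no intensity filter (0.0921), 100 in all 4 arrays (0.105) or a floor of 100 (0.0708), without probesets that can match several transcripts (0.142) and on ranks (0.0668). The medians of the microglia, neuropeptide and interferon lists lay above the spike-in median of 0.36. Those of the other 7 lists called upward lay below it. This ordering does not tell a technical shift from a change, since the median over all tested probesets was -0.04.

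Circadian clock genes were lower as a group: of 16 tested, 0 passed over all probesets, 5 were lower over the list alone, and 13 lay below 0. Hlf (log2 -0.72 ± 0.12, adjusted p = 0.0709), Ciart (log2 -0.68 ± 0.14, adjusted p = 0.0905) and Arntl (log2 -0.41 ± 0.07, adjusted p = 0.0683) did not pass, and the median was -0.26 (adjusted p = 0.00300 by camera, adjusted p = 0.579 with an estimated correlation). Without fluoxetine pool 1 the circadian call was lost (adjusted p = 0.0527). Neocortex markers were also lower: 7 of 7 lay below 0, 0 passed over all probesets, 1 was lower over the list alone, Rasgrf2 (log2 -0.42 ± 0.08, adjusted p = 0.0830), and Tbr1 was at -0.51 ± 0.19 (adjusted p = 0.215). Their median was -0.39 (adjusted p = 0.0344 by camera, adjusted p = 0.647 with an estimated correlation), and the call was lost without control pool 2 (adjusted p = 0.259), without fluoxetine pool 1 (adjusted p = 0.279) and with the mean over each gene's probesets (adjusted p = 0.0575). Of 9 thalamus and habenula markers 1 rose, the neurofilament gene Nefm (log2 0.55 ± 0.07), also when adjusted over the list alone, and camera made no call (adjusted p = 0.119). Of the striatum list 4 members were tested and Penk rose, with 2 higher over the list alone, the other being Ppp1r1b (log2 0.66 ± 0.10, adjusted p = 0.0590). Endoplasmic reticulum stress (15 tested, camera adjusted p = 0.159), oxidative phosphorylation (21, adjusted p = 0.354), cytosolic ribosome (12, adjusted p = 0.871) and Wnt signalling genes (10, adjusted p = 0.885) gave 0 calls by limma over all probesets and over each list alone.

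Camera called 12 of the 31 tested lists, 10 upward and 2 downward, and 0 with an estimated correlation. fry, which asks whether a list's genes move one way on balance without comparing them with other genes, called 4: the neurotrophic and astrocyte lists (adjusted p = 0.0117 each) and the microglia and neuropeptide lists (adjusted p = 0.0168 each). Its mixed test for change in either direction called 24.

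**Figure D3:**
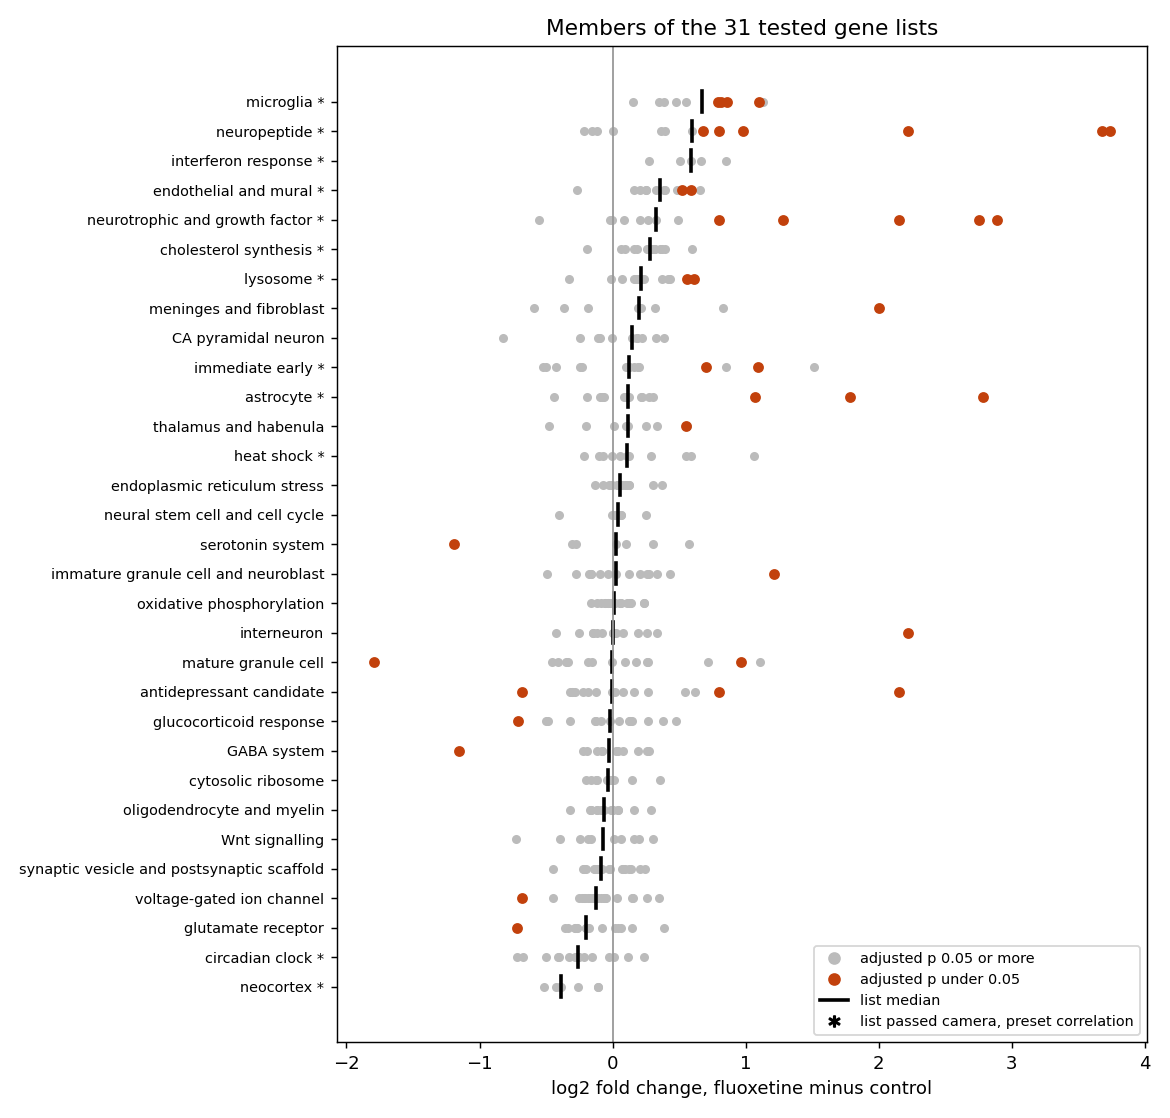
Log2 fold change, fluoxetine minus control, of each tested member (dots) of the 31 tested gene lists, with list medians as black bars. Orange dots have an adjusted p under 0.05 over all probesets and stars mark lists called by camera with a preset correlation. The microglia median of 0.67 is the highest and the neocortex median of -0.39 the lowest.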

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

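In this part, the fits on pools of one number only were chosen after the result was seen. The number called was 0 with no intensity filter (limma, 5396 at an unadjusted p under 0.05), 0 with an ordinary t statistic (2449), 163 with 100 in at least 1 array, 193 without probesets that can match several transcripts, 532 with trend and robust eBayes, 36 with a minimum fold of 1.2, 1145 at an adjusted p under 0.10 (523 higher, 622 lower) and 185 with genes as the unit. Without the filter 45037 probesets were tested, most of them under 100, and the prior degrees of freedom fell from 2.77 to 0.86. Leaving out each array gave 0 to 0 calls, with 1 residual degree of freedom and the lone array assumed to vary like the other group. Simulated data with 3 arrays, control pool 1 left out, still gave 92.2% of changes of log2 2 and 96% of log2 3. Each run planted 200 changes, with log2 2 and 3 as common as log2 0.5 and 1, which eases the adjusted threshold. These data need not hold such a mix. Whether the number of arrays alone accounts for the loss of Penk, Gfap and Bdnf is therefore undecided. The cause of this and of the other differences was not tested. The 2-fold rule took 295 probesets with no filter, 81 with 100 in all 4 arrays, 79 with a pseudocount of 32, 70 where every fluoxetine array was 2-fold from every control array, 138 to 157 with an array left out, and 158 and 183 in the pools numbered 1 and 2. Quantile normalization gave 388 calls, among them 285 of the 291, and median centring 430 with all 291, 67.5% and 65.8% of them higher against 60.1%. Camera called 0 lists with an estimated correlation, fry 4 and its mixed test 24, and 10 to 15 were called with an array left out.

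The pool number as a block left 9 calls, all higher, with 3621 probesets at an unadjusted p under 0.05, and 10 of the 12 lists, without the immediate early (adjusted p = 0.0676) and heat shock (0.0589) lists. Deviations of same-numbered pools correlated at 0.139 over only 2 pairs, which decide nothing, and the labels give the number no meaning. The number was therefore not taken to pair the pools, and whether pools of one number share a cause stays open. The block leaves 1 residual degree of freedom, and the cause of its lower count was not tested. Of 50 called genes named in the text, 42 lost their call under it and 8 kept it. All 50 lost it with no filter and with any array left out, 14 with 100 in at least 1 array (Dsp, Gabrd, Slc27a2, Rasl10a, Kcnk2, Grin3a, Cd53, Ctss, Npc2, Abcc9, Nefm, Rgs2, Rgs10 and Anxa5), 7 with a floor of 100 (Gal, Ecel1, Dsp, Ltk, Zfp772, Trim62 and Anxa4), 4 with array weights, 1 each with the pseudocount and with trend and robust eBayes, and 3 of 39 tested without probesets that can match several transcripts. With quantile normalization, median centring and, for the 35 tested, 100 in all 4 arrays, 0 lost it.

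Tests of several uncalled lists changed direction, at medians near 0 and adjusted p between 0.352 and 0.997, and the cause was not tested. Those medians were -0.038 (CA pyramidal), 0.0022 (serotonin), -0.080 (GABA), -0.0025 (antidepressant candidate) and 0.039 (Wnt) with no filter, -0.079 (GABA) with 100 in at least 1 array, -0.027 (GABA) with quantile normalization and 0.055 (serotonin) with median centring. Without probesets that can match several transcripts they were -0.0038 (mature granule cell) and -0.019 (glucocorticoid). With the block they were 0.027 (serotonin) and -0.019 (glucocorticoid), the latter also with trend and robust eBayes and on ranks. With fry they were 0.027 (serotonin) and -0.027 (GABA), and with the mean over probesets 0.043 (mature granule cell), 0.021 (serotonin), -0.055 (GABA) and -0.025 (synaptic). With an array left out the medians ran from -0.20 to 0.060 (mature granule cell), -0.061 to 0.013 (interneuron), -0.053 to 0.0078 (GABA), -0.10 to 0.052 (glucocorticoid), -0.053 to 0.10 (stem cell), -0.044 to 0.054 (serotonin), -0.046 to -0.023 (ribosome) and, in the called immediate early list, 0.0099 to 0.28. Ttr ran from -1.33 to 2.91 and Pde10a from -0.26 to 0.25, 1 Homer1 probeset was at -0.037, and Pde10a was at 0.00089 with quantile normalization and 0.026 with median centring.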

Other observations

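Of the tests in this part, the one on choroid plexus genes was worded before its result was seen, and its reading for each group and the use of each gene's brightest probeset came after. The tests on gene families, astrocytes and striatum were chosen after. Gene families were formed by symbol stem, and camera called 4 of 288. Collagen genes were higher (14 members, median log2 0.53, adjusted p = 0.000967), with adjusted p = 0.988 with an estimated correlation. Of these 1 rose and 0 fell, Col3a1, with Col4a1, a basement membrane chain chosen after its value was seen, at 0.60 ± 0.09 at its brightest probeset (adjusted p = 0.0590), while its other tested probeset rose by 1.10 ± 0.12 (adjusted p = 0.0380). The Col call held with any array left out and was lost with 100 in all 4 arrays (adjusted p = 0.0839) and without probesets that can match several transcripts (0.107). Regulators of G protein signalling were higher (13 members, median 0.32, adjusted p = 0.0234), with adjusted p = 0.988 with an estimated correlation. Of these 4 rose and 0 fell, Rgs5 and, chosen after their values were seen, Rgs2 (log2 1.17 ± 0.13), Rgs4 (1.01 ± 0.07) and Rgs10 (0.55 ± 0.07), and the call was lost without fluoxetine pool 2 (adjusted p = 0.0854). Annexins were higher (6 members, median 0.70, adjusted p = 0.0234), with adjusted p = 0.988 with an estimated correlation. Of these 2 rose and 0 fell, both chosen after their values were seen: Anxa5 by log2 0.64 ± 0.08 (adjusted p = 0.0460) and Anxa4 at least 1.2-fold (70.7 to 120, adjusted p = 0.0367). The Anxa call was lost with a floor of 100 (adjusted p = 0.0648), without control pool 2 (0.0990) and without fluoxetine pool 1 (0.0556), and too few annexins were left to test with 100 in all 4 arrays or without probesets that can match several transcripts. Zinc finger genes with the stem Zfp were lower (179 members, 136 of them below 0, median -0.10, adjusted p = 0.0380), with adjusted p = 0.988 with an estimated correlation. Of these 0 rose and 1 fell, Zfp772. The Zfp call was lost with 100 in all 4 arrays (adjusted p = 0.123), quantile normalization (median -0.06, adjusted p = 0.110), a floor of 100 (0.0648), the pseudocount (0.0517), trend and robust eBayes (0.0642) and without probesets that can match several transcripts (0.107), and in each fit with an array left out but the one without fluoxetine pool 2. All 4 family directions held under quantile normalization and median centring.

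Gfap, Vim and Aqp4 rose in the fluoxetine pools. A larger share of astrocytes would raise the list's members together, by about as much as Aqp4 (log2 1.07). The median over all 16 tested astrocyte genes was 0.12 (bootstrap 95% interval -0.06 to 0.27). The interval resamples genes and does not cover the spread between pools. For these 16 genes at their brightest probesets, the median argues against a larger share as the whole cause. A change within astrocytes, as in reactive gliosis, may remain, and was not tested.

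Penk, Drd1 and Ppp1r1b, all abundant in striatum, were higher in the fluoxetine pools, and striatal tissue in the dissections is a candidate explanation. An earlier form of the test, set before the genes' group differences were seen, took 7 striatum genes under 100 in all arrays. It counted as arguing against striatal tissue if their median log2 difference was under 0.2 and none reached 100 in both fluoxetine pools. Both were met, with a median of 0.0042, but the second was fixed by the choice of genes under 100. Genes near the floor exclude nothing, so the earlier form was replaced, after the values were seen, by the other 9 measured striatum genes (median 0.0042, 95% interval -0.15 to 0.04). At least 5 of these had to reach the minimum and only 2 did, so the new form could not argue against striatal tissue at any median. Of the 2 that did, Pde10a, chosen after its value was seen, was level at 1952 and 1949, a baseline that could hide a small share. The other, Tac1, is also expressed in hippocampus. Striatal tissue and a response of hippocampal cells to fluoxetine cannot be told apart here.

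Ttr was 18.9-fold higher in pool 1 than in pool 2 of the control group and 11.5-fold in the fluoxetine group. If choroid plexus was left on the tissue of the pools numbered 1, its other genes could be higher there too. Kl and Ecrg4, the only other list members bright enough for the group comparison, were left out when the test was worded. Of the 12 remaining choroid plexus genes, 12 were higher in pool 1 in both groups. Their median log2 difference was 0.67 (0.499 in control and 1.19 in fluoxetine pools). Over both groups the median passed the bound of 0.5, but read for each group, a reading set after the members' values were seen, it was missed in the control pools, and with most of these genes near the floor the explanation stays open. Whether pools of one number share a wider difference stays open too. The second principal component (20.5% of variance) separated pools numbered 1 from those numbered 2 in both groups. The third (15.0%) separated them in opposite directions in control and fluoxetine pools. The first component separated the groups, so the others hold mainly differences between pools of one group. Components without Ttr were not computed. The second component therefore cannot decide whether a difference beyond Ttr is shared.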
